A study of Mus musculus with 6 samples.

How the data were processed

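RNA from primary cultured mouse microglia was profiled on 6 Affymetrix whole-transcript arrays, 3 from fosB-null and 3 from C57BL/6J wild-type cultures. Per the labels' protocols, pups aged 2 days gave the cortical tissue, microglia were collected after 10 days of culture and were replated for 24 h before harvest, and 100 ng of total RNA was amplified into biotinylated sense-strand DNA. The deposited values are on a log2 scale, 1 signal per probe set and array, and were made with Affymetrix Expression Console, per the submitters' processing notes. The version, summary method, normalization and annotation are not given in the sources used here, and the log2 scale was read from the values, which ran from 1.73 to 14.6 with array medians of 7.76 to 7.92. The value table held 35557 probe sets, and none of its columns was left unused.

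Genes were taken from the platform's annotation table. It gave exactly 1 gene symbol to 21789 probe sets, several to 1621 and none to 12147, and the 23410 with at least 1 symbol were tested. Symbols were updated through gene numbers in a RefSeq gene table of assembly GRCm38.p6, which held 21698 of the single-gene probe sets. That table was used only for names and for the order of genes along a chromosome, because the build of the array design is not given in the sources used here. No gene is named from a probe set with several symbols. Where a gene had more than 1 single-gene probe set, the one with the highest mean over all arrays stood for it in lists and in gene order.

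The labels number the arrays 1 to 3 in each group and call them biological replicates. Arrays with the same number held exactly the same value in 45.2% to 51.3% of probe sets, whereas any other pair of arrays shared at most 3 identical values. The deviations from the group means of same-numbered arrays correlated at 0.62, 0.56 and 0.58, so the numbers pair the samples. The pairing comes from the values, as the labels do not say what a number stands for. In 27.8% of tested probe sets the values were identical in all 3 pairs. No source used here records a step that would give so many exact ties, and a difference of 0 within a pair is not a measurement of equality. The ties were more frequent at low signal: in pair 1, 57.0% of probe sets with a mean of 10 or below and 30.6% of those above were tied.

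Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on the deposited log2 values, with no block and no filter on signal. P-values were adjusted by Benjamini-Hochberg over the 23410 tested probe sets, with a threshold of 0.05. Differences are fosB-null minus wild-type on the log2 scale with the standard error of the moderated fit, and group values are means ± SD over 3 arrays. The number of arrays limits the precision. The fit that takes the replicate number as a block was an alternative. Its prior degrees of freedom fell to 0.358, against 2.84 without the block, and was 1.23 with the prior taken only from probe sets that differ in a pair.

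The 22 gene lists and the rule for named genes were fixed before the data were examined. Lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over 21 lists (sex-linked markers were left out of the adjustment), with fry alongside. The lists were the AP-1 family, complement and its receptors, homeostatic microglia, disease-associated and lysosomal microglia, pro-inflammatory mediators, interferon response, antigen presentation, alternative activation, proliferation, immediate early genes, purinergic and glutamate receptors, cholesterol synthesis, unfolded protein and integrated stress response, hypoxia and glycolysis, and markers of astrocytes, oligodendrocyte lineage, neurons, fibroblasts and mural cells, endothelium, border macrophages and blood leukocytes, and sex-linked markers. Named genes are Fosb, C5ar1 and C5ar2, up to 10 genes per direction with the largest fold among single-gene probe sets with adjusted p under 0.05 and non-overlapping groups, a fill to 5 per direction by lowest unadjusted p where fewer passed, and up to 4 members of each list with the lowest p. Predicted genes, olfactory and vomeronasal receptors and small non-coding RNAs are counted but not named unless they are the only calls. Genes named outside this rule are marked as such.

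The 100 nearest measured genes on each side of Fosb were compared with all other measured genes by Fisher's exact test, two-sided, because the null allele was carried through backcrossing. Alternatives were quantile normalization, median centring, a filter on the dimmest 40%, other sets of tested probe sets, an intensity trend, robust eBayes, array weights, the replicate block, leaving out each array, other thresholds, an ordinary per-gene test without moderation, other gene set tests and other numbers of neighbours. A random block on the replicate number, a block with its prior variance from probe sets that differ in a pair, fits without both arrays of 1 number, and fry with the replicate block were added after the data were seen. The steps were tested on simulated data with 23410 genes and the same pairing. The unblocked fit recovered 7.58% of genes changed by 0.5 on the log2 scale, 74.6% of those changed by 1 and 98.5% of those changed by 2, with 0 false calls. The block recovered 63.6%, 71.6% and 91.0% with 18 false calls, and the random block 95.5%, 100% and 100% with 90 false calls. The genes changed numbered 66, 67 and 67, besides 20 members of 1 shifted list. Simulated noise broke the ties of probe sets tied in only 1 or 2 real pairs. The rates with a block may therefore not hold for the deposited values. Camera called the 1 simulated list that was shifted and 0 others. The simulated noise was drawn independently for each gene, so this does not test camera on lists whose members vary together. In the real data the estimated correlation was 0.869 for proliferation and 0.695 for interferon response genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.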

Results

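The data describe microglia, the resident macrophages of the brain, grown from newborn cortex and profiled without further treatment. There were 3 arrays of fosB-null cells, from mice homozygous for a null allele of Fosb backcrossed to C57BL/6J for 20 generations, and 3 of C57BL/6J wild-type cells. Fosb encodes FosB, a member of the AP-1 family of transcription factors that is induced rapidly by stimulation. The design has 1 comparison, fosB-null against wild-type, and the title of the series points to the receptors for the complement fragment C5a, C5ar1 and C5ar2. Arrays are numbered within each group, and same-numbered arrays form 3 pairs.

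The Fosb probe set differed little between the groups. Its log2 signal was 8.02 ± 0.11 in wild-type and 7.90 ± 0.13 in fosB-null arrays (SD, n = 3 each), a difference of -0.12 with a standard error of 0.10. In pairs 1, 2 and 3 the difference was -0.19, -0.09 and -0.09. The limma test gave an unadjusted p of 0.249 and an adjusted p of 1. With the replicate number as a block the limma unadjusted p was 0.0452 and the adjusted p 0.674. With that number as a random block, a fit added after the data were seen, they were 0.00298 and 0.206. The mean signal lay above that of 52.5% of all probe sets. Where this probe set lies relative to the altered part of the allele is not known here, so it does not check the labels.

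C5ar2, which encodes the second C5a receptor, had a lower signal in fosB-null microglia. Its log2 signal was 9.799 ± 0.087 in wild-type and 8.001 ± 0.044 in fosB-null arrays (SD, n = 3 each), a difference of -1.80 with a standard error of 0.07, or 3.48-fold lower. The difference was -1.79, -1.86 and -1.74 in the 3 pairs, and the limma adjusted p was 0.00162. With the replicate number as a block the difference was also -1.80, but the adjusted p was 0.539, from an unadjusted p of 0.000101. A fit added after the data were seen took that block's prior only from probe sets that differ in a pair. Its adjusted p was 0.118. C5ar2 was the only gene past the threshold.

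C5ar1, the main signalling receptor for C5a, had a lower signal in every pair but did not pass the threshold. The log2 signal was 13.03 ± 0.26 in wild-type and 12.13 ± 0.28 in fosB-null arrays (SD, n = 3 each), a difference of -0.90 with a standard error of 0.18, or 1.87-fold lower. The pairs differed by -0.96, -0.82 and -0.93. Its limma adjusted p was 1, from an unadjusted p of 0.00154. With the block the standard error was 0.04, the unadjusted p 0.000823 and the adjusted p 0.674. Map2, with an unadjusted p of 0.376 in that fit, shared the 0.674, so this value does not rank C5ar1. With the replicate number as a random block, a fit added after the data were seen, the adjusted p was 0.00374. On simulated data that fit made 90 false calls, beside recovering 63 of 66, 67 of 67 and 67 of 67 changed genes. C5ar1 and C5ar2 lie 70 and 71 measured genes from Fosb on the same chromosome, and other genes near Fosb also had lower signals.

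**Figure D1:**
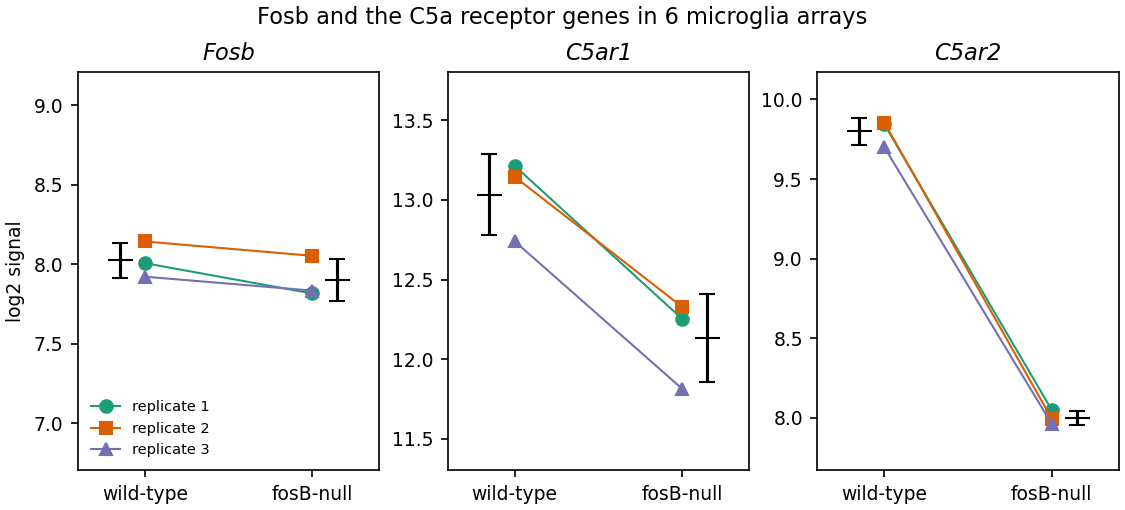
Log2 signal of Fosb, C5ar1 and C5ar2 in each of the 6 arrays, with lines joining same-numbered arrays and black bars for the group mean ± SD (n = 3). C5ar2 lies at 9.799 in wild-type and 8.001 in fosB-null arrays and C5ar1 at 13.03 and 12.13, while Fosb differs by -0.12.

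Across 23410 tested probe sets, limma called 1 gene, which was lower in fosB-null arrays. An unadjusted p under 0.05 was reached by 169 probe sets, 63 higher and 106 lower. Chance gives 1170.5 for independent arrays, which these are not, and in the 3 other splits that part all pairs the same fit gave 89, 19 and 6. The replicate block called 0 genes, with 541 at an unadjusted p under 0.05, and an ordinary test without moderation called 0, with 104. The random block called 47, of which 13 were higher and 34 lower, with 2255 at an unadjusted p under 0.05, 782 higher and 1473 lower. The groups did not overlap in 262 probe sets, or 1.12%, where chance gives 10% for 3 independent arrays against 3, which these paired arrays are not.

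None of the other genes named by rank passed the adjusted threshold. Probe sets with several symbols, genes known only by Gm or Rik numbers and small non-coding RNAs were passed over, some of them with a lower p than genes named here. Of the rest, those with the lowest unadjusted p among lower signals were Ercc2, a DNA helicase of the transcription factor TFIIH, with a difference of -0.59, C5ar1, the zinc finger gene Zfp111 with -0.70, and Cpe, which encodes carboxypeptidase E, with -0.75. Ercc2 and Zfp111 are also neighbours of Fosb. Among higher signals they were the protocadherin gene Fat3 with 0.32, Sgo2a, which protects centromeric cohesin, with 0.46, Pou5f2 with 0.27, the unconventional myosin Myo9a with 0.34 and Atp13a3 with 0.24. A 1.5-fold difference in the same direction in all 3 pairs was found in 5 probe sets, all lower in fosB-null arrays. C5ar2, C5ar1, Cpe and Zfp111 account for 4 of them. The other, which the platform table links to several genes, differed by -2.34, the largest difference of the 5. At least 1 of its genes lies between the outermost neighbours of Fosb. C5ar2, C5ar1 and Zfp111 are neighbours of Fosb too, and Cpe is not.

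Genes around Fosb reached an unadjusted p under 0.05 more often than genes elsewhere. By adjusted p, 1 of the 200 nearest measured genes, C5ar2, passed the threshold against 0 of 19737 others, and with a single call this does not compare the shares. With the replicate block 0 neighbours passed, and with the random block 9 did, each by the probe set that stands for the gene. At the unadjusted threshold there were 17 neighbours, or 8.5%, against 125 of the others, or 0.633% (odds ratio 14.6, Fisher's exact test, two-sided, p = 7.14e-14). The odds ratio was 3.95 with the replicate block, at 8.5% against 2.30%, and 2.75 with the random block, at 22.5% against 9.56%. With single arrays left out it ranged from 5.13 without wild-type replicate 3 to 26.3 without wild-type replicate 1. Of the 17, 16 had lower signals in fosB-null arrays. They included Plaur, the urokinase receptor, with -0.43, Pvr with -0.48, Mark4 with -0.37 and Calm3, a calmodulin gene, with -0.35. The 1 with a higher signal was Kcnn4, a calcium-activated potassium channel, with 0.33. These 5 genes were chosen after their values were seen. Without C5ar1 and C5ar2, 15 of 198 neighbours remained at this threshold (odds ratio 12.9).

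**Figure D2:**
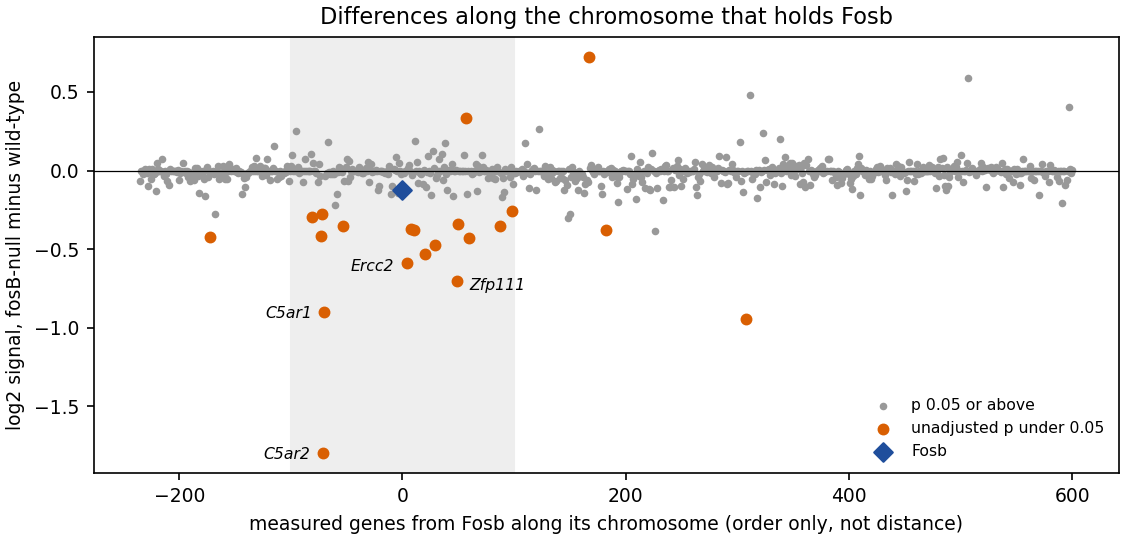
Log2 difference, fosB-null minus wild-type, of each measured gene against its place in gene order from Fosb (diamond), with the 100 genes on each side shaded and genes at an unadjusted limma p under 0.05 in orange. In the shaded part 17 of 200 genes are orange and 16 of them lie below 0.

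Of 21 gene lists, camera with its preset correlation called 11, of which 4 were shifted higher and 7 lower in fosB-null arrays. With an estimated correlation it called 0, and fry called 0, with an adjusted p of 0.994 for every list. Fry with the replicate block, a test added after the data were seen, called 4: complement (adjusted p = 0.00577), AP-1 family (0.0152) and interferon response (0.0484) lower, and unfolded protein and integrated stress response (0.0484) higher. It gave 0.347 for proliferation, 0.0526 for immediate early genes and 0.354 for cholesterol synthesis, and in the 3 other splits that part all pairs it called 0. In those splits camera with its preset correlation called 9, 5 and 3 lists, against 11 in the real one. With the replicate block camera called 4, 3 and 1 there, against 10. Among the members of the 21 lists only C5ar2 passed the threshold over all genes. Adjusted over the list alone, C5ar2 and C5ar1 passed in the complement list, and no member of another list did. The proliferation, interferon, immediate early and cholesterol lists were called whichever single array was left out, and the other 7 lost the call in at least 1 case.

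Proliferation genes were shifted higher in fosB-null arrays, and all 30 measured members had a mean above that of wild-type. The list mean differed by 0.51 and the median by 0.47, with a camera adjusted p of 2.38e-65 and an adjusted p of 0.386 with an estimated correlation. The list mean differed by 0.72 and 0.81 in pairs 1 and 2 and by -0.01 in pair 3. The mitotic cyclin Ccnb2 differed by 0.78, the spindle checkpoint kinase Bub1 by 0.89, Melk by 0.31 and the spindle protein Nusap1 by 0.71, and 0 members passed singly.

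Interferon response genes were shifted lower, with 26 of 27 measured members below wild-type and 1 at a difference of 0. The list mean differed by -0.20, and by -0.27, -0.18 and -0.16 in the pairs (camera adjusted p = 7.62e-18, adjusted p = 0.443 with an estimated correlation). Ifit1, an antiviral effector, differed by -0.59, Rtp4 by -0.68, Oasl2 by -0.54 and Irf7, a transcription factor of the interferon response, by -0.33.

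Immediate early genes, which cells transcribe within minutes of stimulation, were shifted lower, with 22 of 26 below wild-type, 3 above and 1 at a difference of 0. The list mean differed by -0.15, and by -0.14, -0.23 and -0.08 in the pairs (camera adjusted p = 3.55e-13, adjusted p = 0.443 with an estimated correlation). The orphan nuclear receptors Nr4a1 and Nr4a3 differed by -0.92 and -0.42, the phosphatase gene Dusp1 by -0.30 and Fos by -0.33. The AP-1 family, which shares Fos, was shifted lower with 13 of 15 members below wild-type and a list mean of -0.10, or -0.11, -0.14 and -0.05 in the pairs (camera adjusted p = 1e-05, adjusted p = 0.526 with an estimated correlation). Besides Fos and Fosb, Fosl2 differed by -0.31 and Junb by -0.16. Without fosB-null replicate 3 the camera adjusted p of the AP-1 family was 0.0629.

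Cholesterol synthesis genes were shifted lower, with all 20 measured members below wild-type. The list mean differed by -0.12, and by -0.13, -0.26 and 0.01 in the pairs (camera adjusted p = 3.82e-12, adjusted p = 0.443 with an estimated correlation). Hsd17b7 differed by -0.26, Hmgcs1, the synthase ahead of HMG-CoA reductase, by -0.24, squalene epoxidase gene Sqle by -0.25 and Sc5d by -0.17.

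Complement and its receptors were shifted lower by camera (adjusted p = 0.0156, adjusted p = 0.623 with an estimated correlation), with a list mean of -0.12 and a median of 0.00. In the pairs the mean differed by -0.13, -0.10 and -0.14. Of 26 measured members 10 were below wild-type, 9 above and 7 at a difference of 0. Besides the C5a receptors, C2 differed by -0.58 and Fcna by -0.24. Without the neighbours of Fosb, C5ar1 and C5ar2 among them, the camera direction of the list turned and its adjusted p was 0.775. That direction is relative to the other measured genes and does not show that the remaining members had higher signals in fosB-null arrays. With the replicate block its adjusted p was 0.513, with quantile normalization 0.0926 and with median centring 0.0650. The adjusted p was 0.267 without wild-type replicate 2, 0.114 without fosB-null replicate 1 and 0.363 without fosB-null replicate 3.

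Smaller shifts were called for immune lists. Pro-inflammatory mediators had a list mean of -0.05, or -0.03, -0.09 and -0.03 in the pairs, with 20 of 32 members below wild-type (camera adjusted p = 0.0221, adjusted p = 0.623 with an estimated correlation, 0.368 with the replicate block). Ccl5 differed by -0.43, Il1a by -0.42, Il1b by -0.38 and Ptges by -0.20. The call ended with quantile normalization (adjusted p = 0.151), median centring (0.143), the filter on dim probe sets (0.145) and array weights (0.0596). Their adjusted p ranged from 0.000346 to 0.891 when single arrays were left out, and was above 0.05 without wild-type replicate 1 or 2 or fosB-null replicate 3. Antigen presentation genes had a list mean of -0.05, also in each pair, with 11 of 17 below wild-type (camera adjusted p = 0.0154, adjusted p = 0.623 with an estimated correlation, 0.0686 with the replicate block). H2-Q4, Cd86 and Cd74 differed by -0.14 each and Cd80 by -0.13, and with single arrays left out the adjusted p ranged from 0.0129 to 0.290, above 0.05 in all but 2 of the 6 cases.

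The lists shifted higher besides proliferation moved by little. Unfolded protein and integrated stress response genes had a list mean of 0.02, or 0.02, 0.02 and 0.03 in the pairs, with 15 of 24 above wild-type (camera adjusted p = 0.00465, adjusted p = 0.623 with an estimated correlation). Phgdh, of serine synthesis, differed by 0.37, the chaperone genes Hsp90b1 and Hspa5 by 0.22 and 0.13, and the cystine transporter gene Slc7a11 by -0.40. The adjusted p was 0.360 without wild-type replicate 3 and 0.116 without fosB-null replicate 1. Homeostatic microglia genes had a list mean of 0.02, but 0.06, -0.02 and 0.03 in the pairs, with 16 of 24 above wild-type (camera adjusted p = 0.0445, adjusted p = 0.623 with an estimated correlation). P2ry13 differed by 0.27 and Fcrls by 0.13, and Rhob and Slco2b1 by -0.11 and -0.16. With single arrays left out the adjusted p ranged from 0.00540 to 0.422, under 0.05 in 1 of 6 cases.

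Markers of other cells the cultures could hold were compared alongside these lists. Border macrophage markers were shifted higher with a list mean of 0.04, but 0.05, -0.02 and 0.07 in the pairs (camera adjusted p = 0.0111, adjusted p = 0.547 with an estimated correlation). Mrc1 differed by 0.27, Stab1 by 0.18, Siglec1 by 0.15 and Clec4n by -0.24, the last mostly from pair 2 at -0.73. The camera adjusted p of the list with single arrays left out ranged from 0.0116 to 0.229, above 0.05 in all but 2 of the 6 cases. Not called were the markers of astrocytes (list mean 0.00, camera adjusted p = 0.628, 13 of 16 members exactly tied in all pairs), oligodendrocyte lineage (-0.05, 0.0756), neurons (-0.01, 0.777), fibroblasts and mural cells (0.02, 0.140), endothelium (0.01, 0.604) and blood leukocytes (0.01, 0.262). With the replicate block, the fibroblast and mural list had an adjusted p of 0.0474 and the blood leukocyte list 0.0258, both higher, but with an estimated correlation as well the adjusted p was 0.519 and 0.466. The oligodendrocyte list was called lower with array weights (adjusted p = 0.0174), with the filter on dim probe sets (0.0440) and without wild-type replicate 3 (0.0431). Without both arrays of replicate 3 it was also called lower (0.0119), and the fibroblast and mural list was called higher (0.0412). The neuron list had a mean below 0, a median of 0.00 and a camera direction above. The members with the lowest p were Aldoc, Atp1b2, Mlc1 and Slc1a2 for astrocytes, with differences of 0.01, -0.01, 0.00 and 0.00, and Mbp, Cspg4, Mag and Mog for oligodendrocytes, with -0.21, -0.20, -0.15 and -0.05. For neurons Syp, Map2, Tubb3 and Stmn2 differed by 0.09, -0.06, 0.02 and -0.09. For fibroblasts and mural cells Igfbp5, Igfbp4, Acta2 and Postn differed by -0.33, 0.13, 0.11 and 0.26. For endothelium Kdr, Vwf, Flt1 and Pecam1 differed by -0.08, 0.12, 0.08 and -0.07. For blood leukocytes Ccr2, Ngp, Cd3g and Mpo differed by 0.05, 0.03, 0.03 and -0.02. Several of these small differences change sign when an array is left out or the arrays are rescaled. Some rest on a single pair, with exact ties in the others: pair 1 for Mag and Ngp, pair 2 for Map2, Tubb3, Stmn2, Vwf and Pecam1, and pair 3 for Aldoc, Atp1b2 and Mpo.

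The remaining lists were not called over all 6 arrays. Disease-associated and lysosomal microglia genes had a list mean of 0.04 (camera adjusted p = 0.155), with Ch25h, the cholesterol 25-hydroxylase gene, at 0.65, Cst7 at 0.28, Ctsl at -0.12 and Apoe at -0.10. It was called higher without wild-type replicate 1 (adjusted p = 0.0129) and without fosB-null replicate 3 (0.000417). Alternative activation genes had a mean of 0.02 (adjusted p = 0.140), with Cd200r1 at 0.16, Mgl2 at 0.06 and Ccl24 at 0.05. Mgl2 and Ccl24 differed in a single pair and were exactly tied in the others. Purinergic and glutamate receptors had a mean of 0.01 (adjusted p = 0.424), with P2ry2 at -0.14, Entpd1 at -0.15 and P2ry6 at 0.07. They were called higher without wild-type replicate 3 (adjusted p = 0.0431). Hypoxia and glycolysis genes had a mean of -0.01, a median of 0.02 and a camera direction above 0 (adjusted p = 0.628), with Vegfa at -0.19, Bnip3 at -0.18, Pfkfb3 at -0.14 and Hmox1 at -0.09.

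Sex-linked probe sets differed within pairs. Xist, which is transcribed from the inactive X chromosome, differed by -0.10, 0.47 and 1.00 in pairs 1, 2 and 3. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty differed by -0.06, -0.38 and -0.58. Over the groups Eif2s3y differed by -0.47, Kdm5d by -0.33, Uty by -0.22 and Xist by 0.45, and 0 of these passed the adjusted threshold.

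**Figure D3:**
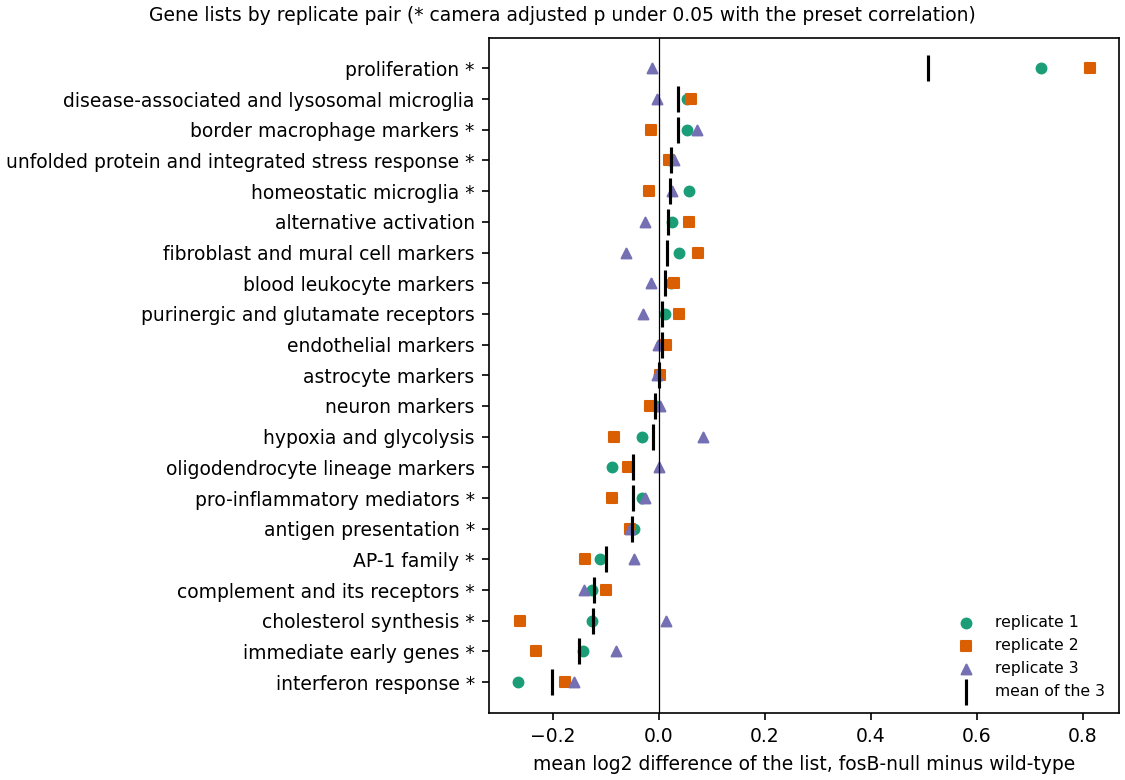
Mean log2 difference, fosB-null minus wild-type, of each of 21 gene lists in the 3 replicate pairs (symbols) and over them (black bars), with stars for lists called by camera at the preset correlation. Proliferation lies at 0.72 and 0.81 in pairs 1 and 2 and at -0.01 in pair 3, and interferon response lies below 0 in all 3.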

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

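The random block, the block with another prior, the fits without both arrays of 1 number, the block with an estimated correlation, fry with the replicate block and the lists without neighbours of Fosb were chosen after seeing the data. The number of genes called was 0 with the replicate block, 47 with the random block, 0 with the block whose prior came from probe sets that differ in a pair, 11 at an unadjusted p under 0.01 with at least 1.5-fold, and 0 with the ordinary test, and 1 in the other settings that keep all arrays. It ranged from 0 to 2 when arrays were left out, with 2 without wild-type replicate 3 and 0 whenever both arrays of a number were left out. C5ar2 kept a difference of -1.80 with the replicate block (adjusted p = 0.539) and with the other prior (adjusted p = 0.118), and its difference ranged from -1.85 to -1.77 when arrays were left out. Its call ended without both arrays of any 1 number, where fewer samples remain. C5ar1 had -0.90 and an adjusted p of 0.00374 with the random block. The number of lists called was 0 with an estimated correlation, 0 with fry and 0 with the block and an estimated correlation, and ranged from 6 to 11 when arrays were left out, with 6 without fosB-null replicate 1 and 6 without fosB-null replicate 3. With the replicate block it was 10, and 4 by fry with that block. The camera direction of the complement list, which is relative to other genes, turned without the neighbours of Fosb (adjusted p = 0.775). The removal of C5ar1 and C5ar2 accounts for that by construction. Leaving out both arrays of a number also ended, in at least 1 case, the calls of the complement, pro-inflammatory, antigen presentation, homeostatic, unfolded protein and border macrophage lists. It gave new calls to the oligodendrocyte and the fibroblast and mural lists without replicate 3, and to the hypoxia list without replicate 2. Among genes neighbouring Fosb, the adjusted threshold was passed by 1, by 0 with 50 neighbours on each side, where C5ar2 is no longer among them, 0 with the replicate block, 9 with the random block, counting only the probe set that stands for each gene, 0 with the other prior, and 0 to 1 when arrays were left out. At an unadjusted p under 0.05 it was 17, 7 with 50 neighbours on each side, 17 with the replicate block, 45 with the random block, 29 with the other prior and 12 to 17 when arrays were left out. For changes with no reason given, the cause was not tested.

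Named genes kept their direction and side of the threshold in 1797 comparisons with alternatives, gained a call in 8 and lost it in 5, and 34 changed sign, all of them marker genes with no call. Aldoc was at -0.013 with quantile normalization and -0.017 with median centring, Mlc1 at -0.015, -0.021 and, with array weights, -0.0031, Tubb3 at -0.00033 with median centring and Cd3g at -0.0035 with quantile normalization. With arrays left out, Aldoc ranged from -0.0071 to 0.024, Atp1b2 from -0.096 to 0.077, Mlc1 from -0.028 to 0.050, Mag from -0.41 to 0.030, Syp from -0.014 to 0.17, Stmn2 from -0.31 to 0.12, Flt1 from -0.025 to 0.18, Pecam1 from -0.17 to 0.081, Ccr2 from -0.015 to 0.090, Ngp from -0.085 to 0.17, Cd3g from -0.078 to 0.12 and Mpo from -0.11 to 0.053. The lists kept direction and side in 367 comparisons. Among these are the intensity trend, the single-gene probe sets alone and every row of the value table, where each camera result was the same by construction. Those settings therefore do not test the lists. The lists lost the call in 79 comparisons, gained one in 11 and turned direction in 26, of which all but that of the complement list were lists with no call before or after. The adjusted p was 0.763 for the astrocyte list with quantile normalization, 0.814 for the hypoxia list with array weights, and for the neuron list 0.763 with quantile normalization, 0.900 with the replicate block, 0.994 with fry, 0.347 by fry with the block and 0.905 with the block and an estimated correlation. For alternative activation it was 0.939 by fry with the block. With arrays left out, the adjusted p of lists that turned in at least 1 case ranged from 0.126 to 0.796 for astrocytes, 0.176 to 0.958 for neurons, 0.259 to 0.882 for endothelium, 0.0589 to 0.958 for blood leukocytes, 0.000417 to 0.894 for disease-associated microglia, 0.0431 to 0.935 for purinergic and glutamate receptors and 0.00345 to 0.882 for hypoxia, with the calls at the lower ends in the main direction. The alternative log2 of the value plus a constant was not run because the values are already log2. Signal over background is not given for these values, so dim probe sets were not set apart beyond the filter on the dimmest 40%.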

Other observations

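The tests of explanations for the neighbours of Fosb, C5ar1 and C5ar2, proliferation and the interferon list were chosen after the results were seen. The comparison of the 200 neighbours with other genes, from which the odds ratio comes, had been planned before. The test on X-linked escape genes and the counts over splits were set before their results.

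Fat3 was measured by 15 single-gene probe sets, and all had a higher mean in fosB-null arrays, from 0.06 to 0.32, with 0 past the adjusted threshold. With the random block 47 probe sets of 43 genes passed, 11 of them linked to genes between the outermost of the 200 neighbours of Fosb, of which 9 stand for their gene in gene order. Besides those already named they included the adaptor gene Nck2, the Fc receptor gene Fcgr4 and the integrin gene Itga4. These names were chosen after their values were seen. The fit that called them made 90 false calls on simulated data, beside the 63, 67 and 67 changed genes it recovered. Among the 12147 probe sets without a gene in the platform table, limma called 0. An unadjusted p under 0.05 was reached by 595 of them, of which 466 were higher in fosB-null arrays. Chance gives 607.35 for independent arrays, which these are not, and the tested probe sets gave 169 against 1170.5. The 595 are therefore not shown to be at the level of chance, and their cause was not tested.

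Lower signals lay on both sides of Fosb along chromosome 7, but on 1 side none was found next to it. The 52 nearest genes before Fosb held 0 at an unadjusted p under 0.05, and all 7 within 50 genes came after it. Several of these 52, Ceacam3 and Psg18 among them, had a difference of exactly 0, so the stretch is not shown to lack an effect. Of the 85 other windows of 201 measured genes, 0 held as many genes at an unadjusted p under 0.05, and the highest held 6, which argues against a chance position. An effect of Fosb loss that ignores position is argued against as the whole cause by an odds ratio of 14.6 with a lower 95% bound of 8.06, although that bound was 2.78 without wild-type replicate 3, 2.23 with the replicate block and 1.92 with the random block. Donor-strain DNA linked to the null allele is a candidate explanation: the excess was on both sides of Fosb (the larger Fisher's exact p was 5.68e-05) and ended beyond 200 genes, at 0.450% of genes against 0.640% on other chromosomes, though a local effect of the altered allele on nearby genes was not tested and the donor strain is not given in the sources used here. For C5ar1 and C5ar2, at most 71 genes from Fosb and beyond those 52 genes, loss of FosB and linked DNA cannot be told apart. Any donor DNA linked to the allele would be in every fosB-null array.

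The sex-linked differences in pairs 2 and 3 may come from unequal shares of male and female pups, since X-linked genes that escape inactivation differed by a mean of 0.0915 in these pairs against 0.00895 in pair 1. These were only 4 genes, Kdm6a was exactly tied in pairs 1 and 2 and Kdm5c in pair 2, and the mean of 0.047 in pair 2 comes mostly from Eif2s3x at 0.18. That does not account for the C5a receptors, as C5ar2 differed by -1.79 and C5ar1 by -0.96 in pair 1, where sex-linked probe sets were nearly level. Nor does it account for the interferon list, which differed by -0.265 in pair 1 and by a mean of -0.168 in the others. An effect of the genotype on the interferon list stays open.

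The proliferation list was higher in fosB-null arrays of pairs 1 and 2 only. Variation between cultures stays open: the list mean varied by 0.736 among the 3 wild-type arrays and differed by 0.767 within these pairs, but the former is a spread between pairs, and no pair holds more than 1 array of a genotype to give the spread within one. More astrocytes in the fosB-null cultures stay open too: the astrocyte markers differed by a mean of 0.00168 in these pairs, but 15 of 16 held exactly tied values there, which measures no equality. In wild-type arrays Aldoc lay at 8.15 and Aldh1l1, named after its values were seen, at 8.27. An effect of the genotype on cell division stays open.

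The 6 arrays can be split into 3 against 3 in 10 ways, too few for a share under 0.05. For genes called, 1 split was as large, the real one, with 1 gene against at most 0 in the others. For gene lists 1 split was as large, again the real one, with 11 lists against at most 9. For neighbours of Fosb at an unadjusted p under 0.05, 7 splits were as large, with 17 in the real split and at most 35 in another. The splits that keep a pair together gave 1973 to 3960 probe sets at an unadjusted p under 0.05 against 169 in the real one, which points to the pairing of the arrays. Of the 4 splits that part all pairs, the real one gave 17 neighbours and the others 0, and with the random block 47 calls against at most 8.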
